A study of Mus musculus with 2 samples.

How the data were processed

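Polyadenylated mRNA of whole lung tissue from 1 adult female C57BL/6J mouse was sequenced in 2 libraries. Per the labels they are technical replicates 1 and 2 of biological replicate 1, and the RNA was extracted with a column kit for lipid-rich tissue. Both libraries form 1 group, and no comparison of conditions exists. The labels do not say whether the libraries share 1 RNA extraction, so a difference between them can arise at any step after the tissue was taken.

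The authors deposited 1 gene table and 1 transcript table per library, and per the labels and the deposited file descriptions both use the mouse assembly mm10 and annotation release M4. The aligner, the quantifier and their versions are not given in the sources used here. Expected counts are, per the file headers, the authors' estimates of reads per gene or transcript, with reads that match several places divided between them. TPM values are, per the file headers, abundances per 1000000 transcripts computed by the authors, deposited both as the usual estimate and as a posterior mean. FPKM values are, per the file headers, the authors' abundances per kilobase and 1000000 fragments. The percent of its gene's abundance that each transcript holds was deposited by the authors, and so were lengths and effective lengths in bases. The effective lengths imply a mean fragment length of 179 bases in replicate 1 and 184 bases in replicate 2. Of the expected counts above 0, 92.1% in replicate 1 and 89.2% in replicate 2 lay within 0.005 of a whole number. The tables have 43346 gene rows, 26248 numbered rows and 97 spike-in rows, and the last 2 kinds were at 0 throughout and left out.

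Gene symbols, positions and transcript sequences came from GENCODE release M21 on GRCm38, the same assembly as mm10 under another name. By gene identifier 42462 of 43346 genes matched. GC content was computed from the reference transcripts of each gene as the mean over its annotated transcripts, and 50699 of 51565 expressed transcripts had a sequence. Of all 51565 expressed transcripts, 85.1% had the same length in the reference as in the deposited table. Gucy1a3 and Cyr61 were matched as Gucy1a1 and Ccn1, and Rn7sl1 was not matched.

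Expected counts were rounded to whole numbers. Libraries were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 0.913 and 1.10, and the log2 ratio of replicate 2 over replicate 1 was taken with a prior of 0.5 counts. Ratios use counts and are not corrected for a change in the main transcript, so they can differ from ratios of TPM. Genes with a mean TPM of at least 1 over both libraries were tested. With 1 library on each side a difference between libraries has no replicate check, so no p-value is given for a gene. An exact two-sided binomial test against the scaled library sizes, adjusted by Benjamini and Hochberg at 0.05, measured the excess over counting noise only. Dispersion was estimated with edgeR for an intercept-only design, which leaves 1 residual degree of freedom per gene shared over genes. Gene lists with at least 5 tested members were placed among 10000 random lists of the same size, matched in 20 classes of mean TPM. The trend on GC content was a lowess fit with a span of 0.3, and bootstrap intervals used 1000 draws of genes. A second measure of GC content was the 10th percentile over windows of 180 bases, taken every 10 bases along each transcript. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

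Intervals of ratios and shares are exact Clopper-Pearson intervals at 95%. A fold against 0 counts was computed against 3 counts per library and is a lower bound at that floor only. The exact 95% interval reaches lower, for Igfbp6 to 1154-fold where the floor gives 1420-fold. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The totals of 16104440 and 17110880 expected counts put that floor at 0.186 and 0.175 CPM.

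The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for the alternatives that subtract a trend on GC content or keep the middle GC decile, and for the tests of explanations, which were chosen later. Genes were named if they were among the 15 of highest mean TPM outside the mitochondrial genome, among the 4 members of highest mean TPM of a list or below a TPM of 1 in both libraries, among the 10 highest or 10 lowest ratios with at least 100 counts over both libraries, or on the list for the label female. Up to 6 named genes with differing main transcripts were added. Some genes that met these rules are withheld and not reported here. The lists cover 17 cell types of the lung, blood and neighbouring tissues (erythroid, platelet, cardiac and skeletal muscle, adipose, thymocyte, liver, squamous and thyroid), and states or technical classes (mitochondrially encoded mRNAs, ribosomal proteins, histones, immediate early, heat shock, proliferation, circadian and interferon-stimulated genes, long nuclear RNAs, small structured RNAs). Several lists were not placed among random lists because fewer than 5 members were tested.

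Alternatives were DESeq2 1.42.0 size factors, total counts or TPM ratios in place of TMM, other priors, pseudocounts and filters on low values, FPKM, CPM or posterior mean TPM as the unit, TPM without mitochondrial genes, random lists matched on length, stricter limits for transcripts, and each library alone. The steps were tested on simulated data. In counts drawn for 14139 genes, with 100 genes raised 4-fold and 100 lowered 4-fold, the binomial test called 99% and 92% of them and 0.0430% of unchanged genes. A simulated coefficient of variation of 0.2 was recovered as 0.200. Of 200 random lists of 12 genes 4% fell outside the 95% range, and 100% of lists shifted by 4 on the log2 scale did. A shift of 4 is beyond the random range of lists of like size, so this outcome says nothing of smaller shifts. The simulations were easier than the data, where the coefficient of variation was 1.03 and most genes differed. The binomial simulation was scaled on its unchanged genes and not with TMM.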

Results

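Polyadenylated RNA from the lung of 1 adult female mouse of the inbred strain C57BL/6J, aged 10 weeks, was sequenced in 2 libraries, technical replicates 1 and 2 of a single biological replicate. Per the labels, replicate 2 was made later than replicate 1. The libraries held 16104440 and 17110880 expected counts in all, and expected counts above 0 were recorded for 17892 and 19597 genes. The design has 1 group, so its content is the set of genes expressed in this lung and how far the libraries differed in measuring them. With 1 animal there is no biological replication, and every SD below is over n = 2 libraries and measures the spread between technical replicates, not between animals.

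Secreted products of the airway and alveolar epithelium were among the genes of highest mean expression, in an order that differed between the libraries. Scgb1a1, the secretoglobin of airway club cells (ENSMUSG00000024653.2, chromosome 19, 9083636 to 9087958 on the reference assembly GRCm38), had the highest mean of any gene outside the mitochondrial genome, at 95877 ± 110845 TPM, from 17498 TPM in replicate 1 and 174257 TPM in replicate 2. Sftpc, surfactant protein C of alveolar type 2 cells (ENSMUSG00000022097.3, chromosome 14, 70520949 to 70524081), was at 287 TPM in replicate 1 and 39612 TPM in replicate 2. Lyz2, a lysozyme of macrophages and type 2 cells, was at 5716 and 11487 TPM, and Scgb3a2, another club cell secretoglobin, was at 4671 and 4406 TPM. In replicate 1 Tpt1, at 18459 TPM, was above Scgb1a1, and Rps24 was at 10486 TPM. Among the other genes of highest mean were Tpt1, Rps24, Tmsb4x and Eef1a1, which are abundant in most tissues, and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2. Gm28661, Gm10925, Gm28437 and Gm28438, annotated as pseudogenes on chromosome 1 between positions 24612775 and 24615565, were also in this group. In replicate 1 these were at 30251 to 43111 TPM, all above Scgb1a1. They are copies of mitochondrial sequence, so their reads can belong to the mitochondrial genes and their levels are uncertain.

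At a TPM of at least 1, 12131 genes were detected in replicate 1 and 14096 in replicate 2. Of these, 11356 were detected in both libraries, 775 in replicate 1 alone and 2740 in replicate 2 alone. Among 21474 protein-coding genes, 10713 were detected in both, 501 in replicate 1 alone and 2302 in replicate 2 alone. A gene at 0 counts can still be present at up to 3 counts, which is 0.186 CPM, the count scaled to a total of 1000000, in replicate 1 and 0.175 CPM in replicate 2.

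Airway and alveolar epithelial genes were expressed in both libraries, with larger sums in replicate 2. The club cell genes summed to 25107 TPM in replicate 1 and 190879 TPM in replicate 2, and 10 of the 12 listed genes reached a TPM of 1 in both. Cbr2, a carbonyl reductase of club cells, was at 70.0 and 5389 TPM, whereas Aldh1a1, a retinaldehyde dehydrogenase, was at 1785 and 732 TPM. The alveolar type 2 genes summed to 8199 and 50915 TPM, and all 13 were detected in both libraries. Sftpb, which encodes surfactant protein B, was at 48.3 and 2493 TPM, Sftpa1 was at 1808 and 4344 TPM, and the chemokine gene Cxcl15 was at 3288 and 1158 TPM. The alveolar type 1 genes summed to 2348 and 5560 TPM, with Ager (chromosome 17, 34597862 to 34600936), a receptor gene and standard type 1 marker, at 13.7 and 2508 TPM and Hopx at 639 and 1090 TPM. Ciliated cell genes summed to 352 and 1097 TPM, with the tubulin-binding gene Tppp3 at 1.15 and 547 TPM and the dynein light chain gene Dynlrb2 at 89.3 and 164 TPM. Goblet, basal and neuroendocrine genes were low, with sums of 7.04 and 19.2 TPM. Agr2 at 1.33 and 6.33 TPM and Calca at 3.28 and 3.66 TPM were detected in both libraries, Muc5b reached 3.04 TPM in replicate 2, and Muc5ac, Krt5, Krt14, Krt15 and Chga were below a TPM of 1 in both libraries.

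Among endothelial and stromal genes the order of the libraries varied by list. Alveolar capillary genes summed to 5295 TPM in replicate 1 and 2257 TPM in replicate 2. Hpgd, a prostaglandin dehydrogenase, was at 1577 and 390 TPM, and Calcrl, an adrenomedullin receptor component (chromosome 2, 84330626 to 84425411), at 1410 and 242 TPM. Pan-endothelial genes, by contrast, summed to 802 and 2941 TPM, with the tight junction gene Cldn5 (chromosome 16, 18776847 to 18778262) at 0.43 and 607 TPM and Pecam1 at 74.4 and 219 TPM. The median GC content of annotated transcripts was 47.7% in the capillary list and 55.7% in the pan-endothelial list. Lymphatic endothelial genes summed to 45.7 and 207 TPM, most of it Ccl21a in replicate 2, at 165 TPM. Fibroblast and matrix genes summed to 2809 and 7067 TPM, led by the methyltransferase gene Inmt at 1169 and 3674 TPM, and the proteoglycan gene Dcn was at 557 and 203 TPM. Smooth muscle and pericyte genes summed to 851 and 1310 TPM, with smooth muscle actin, Acta2, at 37.0 and 335 TPM and Postn at 533 and 129 TPM. Mesothelial genes summed to 261 and 321 TPM, with Gpm6a at 176 and 29.9 TPM and Krt19 at 4.69 and 157 TPM.

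Immune genes were expressed in both libraries, and the order of their lists differed between them. Alveolar macrophage genes summed to 2922 TPM in replicate 1 and 2062 TPM in replicate 2, with the chitinase-like gene Chil3 at 1766 and 941 TPM and the protease gene Ctsd at 24.8 and 530 TPM. Ear1 and Ear2, ribonuclease genes on the same list, are close paralogs whose division of reads is uncertain. Genes of monocytes, interstitial macrophages and dendritic cells summed to 501 and 3109 TPM, with Cd74, the class II invariant chain, at 21.9 and 1464 TPM and H2-Aa at 224 and 600 TPM. B and plasma cell genes summed to 743 and 2396 TPM, with Igkc at 146 and 1492 TPM and Jchain at 285 and 103 TPM. Neutrophil genes summed to 1206 and 801 TPM, mainly the calprotectin subunits S100a8, at 853 and 320 TPM, and S100a9, at 247 and 343 TPM, while Ly6g, Ngp and Camp were below a TPM of 1 in both. T and NK cell genes summed to 244 and 271 TPM, with Gzma at 153 and 66.5 TPM. Mast cell, basophil and eosinophil genes summed to 41.4 and 73.9 TPM, with the histidine decarboxylase gene Hdc at 27.1 and 61.4 TPM. The 17 cell type lists together, 217 genes, held 5.17% of all TPM in replicate 1 and 27.1% in replicate 2, a mean of 16.2% ± 15.5 (SD, n = 2). Much of this was Scgb1a1, with 1.75% and 17.4% of all TPM, and Sftpc, with 0.0287% and 3.96%. In CPM in place of TPM the mean share of the lists was 9.29%.

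Genes listed for blood and for tissues next to the lung were also expressed. The values do not show whether these RNAs came from such tissues or from cells within the lung. Erythroid genes summed to 2081 TPM in replicate 1 and 41602 TPM in replicate 2, of which haemoglobin took nearly all. Hbb-bs was at 1765 and 15820 TPM, Hba-a1 at 128 and 8580 TPM and Hba-a2 (chromosome 11, 32296489 to 32297298) at 5.10 and 13710 TPM, and the division of reads within each haemoglobin pair is uncertain. Cardiac muscle genes summed to 184 and 1565 TPM, and 12 of the 14 listed reached a TPM of 1 in replicate 2. Myl7, the atrial myosin light chain (chromosome 11, 5896637 to 5898782), was at 18.5 and 465 TPM, Actc1 at 66.0 and 191 TPM and Myl4 at 6.50 and 257 TPM. The only listed gene below a TPM of 1 in both was Myl2, a ventricular light chain. Adipose genes summed to 947 and 1513 TPM, with Fabp4 at 460 and 478 TPM and Adipoq at 99.96 and 90.1 TPM. Platelet genes summed to 65.2 and 81.8 TPM, and liver genes to 68.6 and 66.1 TPM, nearly all of it Cyp2e1, which the lung also expresses, at 66.7 and 60.03 TPM. Thymocyte genes summed to 42.3 and 16.7 TPM, nearly all of it Cd1d1, at 39.3 and 15.8 TPM, and Rag1, Rag2 and Ptcra were below a TPM of 1 in both. Skeletal muscle genes summed to 9.45 and 39.7 TPM, and genes of squamous epithelium and thyroid to 0.32 and 2.43 TPM.

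**Figure D1:**
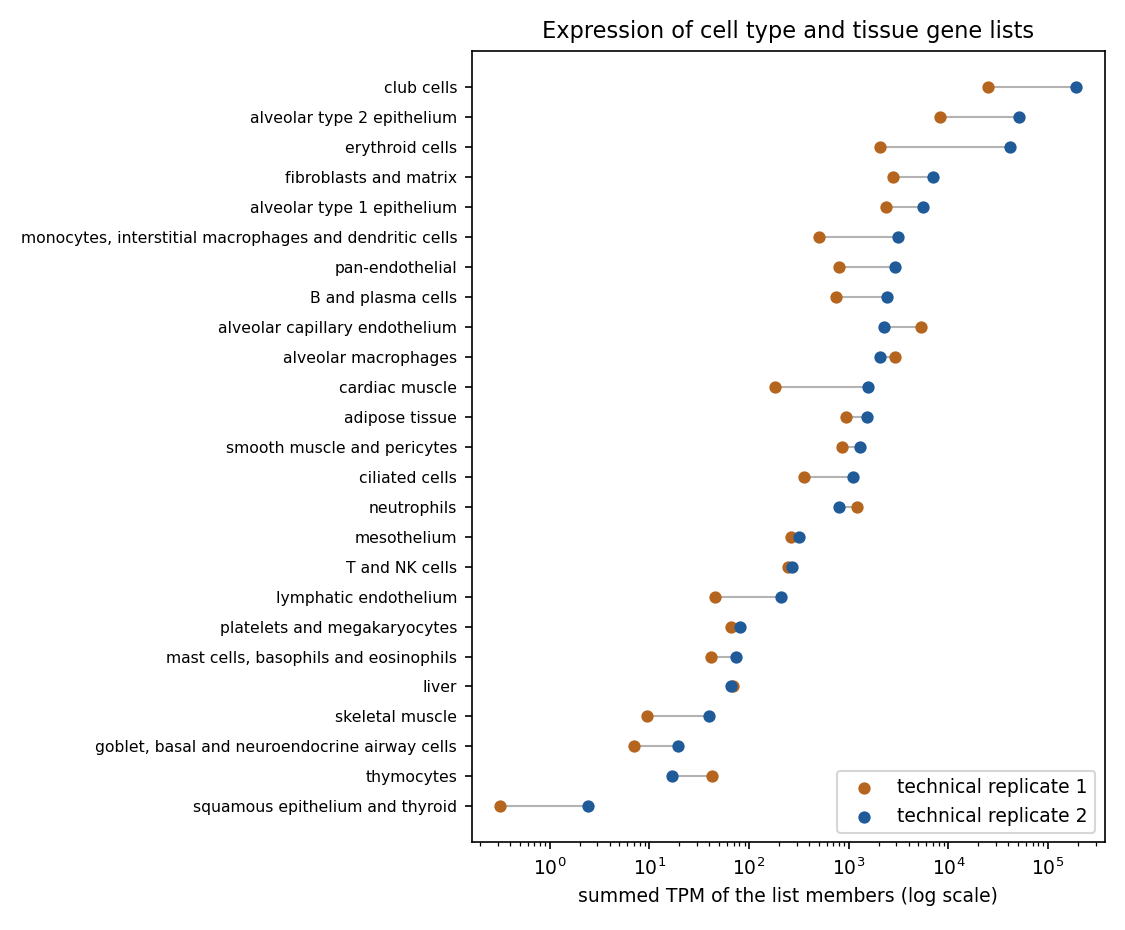
Summed TPM of each cell type or tissue gene list (x axis, log scale) in technical replicate 1 (brown) and technical replicate 2 (blue), 1 point per library, joined by a line. Club cell genes are the highest in both libraries, at 25107 and 190879 TPM, and the capillary endothelial list is among those with the larger sum in replicate 1.

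The only contrast between libraries in this design is that between the technical replicates, which asks how closely they measure the same lung. They differed over 2-fold for most genes as measured. Of 14139 genes with a mean TPM of at least 1, 5553 were over 2-fold higher in replicate 2, 3990 were over 2-fold lower and 4596 lay within 2-fold, so 67.5% differed over 2-fold. With genes at 0 set to 3 counts, 5515 were over 2-fold higher and 4000 over 2-fold lower. The scaled ratios had a median log2 of 0.19, which is not subtracted from the ratios below, and scaling by total counts or by TPM put this median at 0.45 and 0.01. The balance of directions depended on the setting, with 5988 genes higher and 3171 lower by total counts, 5265 and 4507 by TPM ratio, and 2620 and 2630 of 7696 genes at a mean TPM of at least 10. The share over 2-fold apart was 40.8% with a trend on GC content subtracted, 34.6% with a trend on the GC content of the most AT-rich windows subtracted and 44.6% in the middle GC decile, alternatives chosen after seeing the data.

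The highest ratios belonged to genes nearly without reads in replicate 1. Igfbp6, an insulin-like growth factor binding protein gene (chromosome 15, 102144362 to 102149511), had 0 counts in replicate 1 and 5428 in replicate 2, at least 1420-fold higher, and the elastin gene Eln (chromosome 5, 134702593 to 134747323) had 0 and 2791 counts, at least 730-fold higher. Chchd10, Map3k11, Mbd3, Ptov1 and Gga1 also had 0 counts in replicate 1 and were at least 409-fold to 454-fold higher in replicate 2. The ribosomal protein gene Rps15 (chromosome 10, 80292453 to 80294114) had 3 and 16475 counts, a ratio of 4310 with a 95% counting interval of 1474 to 20899.7. The ferritin gene Ftl1 had 10 and 33502 counts, a 2629-fold difference (1429 to 5483). Hba-a2 had 21 and 80250 counts, a 2999-fold difference (1962 to 4845), which can depend on how reads were divided with Hba-a1. Hba-a1 itself had 744 and 68859 counts, a 72.6-fold difference (67.6 to 78.2). In all, 240 genes were at 0 in replicate 1 with at least 100 counts in replicate 2. In the other direction there were 5 such genes, Gm28439, Gm4294, Zfp708, Hist2h3c1 and Gm20547, several of them copies of other genes whose reads can be divided differently. Adnp, which encodes a homeobox transcription factor (chromosome 2, 168180986 to 168207112), was 36.8-fold lower in replicate 2 (28.7 to 47.9), with 1878 and 65 counts. Gm3362, Gm13502, Gm28037 and Gm9762 completed the 10 lowest ratios, and the first of these had 303 and 1 counts.

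The difference exceeded counting noise for most genes. An exact two-sided binomial test of the reads, which compares these libraries and not conditions, called 12677 of 14139 genes after Benjamini-Hochberg adjustment at 0.05, or 89.7%, and 12713 before adjustment. Of the genes called, 6760 were higher and 5917 lower in replicate 2. Across 20561 genes above 0 in at least 1 library, log2(TPM + 1) had Pearson's r = 0.744 (bootstrap interval over genes 0.736 to 0.751) and Spearman's rho = 0.740; genes are not independent replicates. Restricted to genes with a mean TPM of at least 1, r was 0.563. The coefficient of variation between the libraries beyond counting noise, estimated with edgeR, was 1.03, and the chi-square statistic was 657 per gene over 16225 genes, so the files do not hold a single library deposited under both labels.

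Some gene lists differed between the libraries more than random lists of like expression. The listed ribosomal protein genes had a median log2 ratio of 5.27, with 24 of 28 genes over 2-fold higher in replicate 2 and 1 lower. Rplp1, Rps29 and Rps14 were 51.7-fold, 97.3-fold and 104-fold higher. The list is a part of the ribosomal protein genes, and Rps24, outside it, was 2.03-fold lower, at 10486 and 4341 TPM. Cardiac muscle genes had a median of 4.20, with 11 of 13 genes over 2-fold higher and Myl7 at 27.6-fold (22.2 to 34.6). Club cell genes had a median of 3.44, with 7 of 11 genes higher. Scgb1a1 was at 10.9-fold (10.8 to 11.0) and Cbr2 at 146-fold (132 to 162), while Aldh1a1 was 2.21-fold lower. Erythroid genes had a median of 3.14. Smooth muscle and pericyte genes had a median of 3.13, with 11 of 14 genes higher and Acta2 at 10.0-fold (9.25 to 10.8). Pan-endothelial genes had a median of 2.18, with 8 of 14 genes higher and Egfl7 at 26.0-fold (23.2 to 29.2). All 13 mitochondrially encoded mRNAs were over 2-fold lower in replicate 2, with a median of -2.52, and they took 16.6% of all TPM in replicate 1 and 2.29% in replicate 2. The cytochrome oxidase gene mt-Co1 was 5.18-fold lower and the complex I gene mt-Nd2 was 8.20-fold lower.

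Among 10000 random lists of the same size and expression, the medians of the first 6 of these lists lay between the 98.7th and 100th percentiles and that of the mitochondrial list at percentile 0. Of these 7 calls 5 held with the GC trend subtracted and 3 with the window trend, as given below. The other 21 of the 28 lists tested lay within the central 95% of random lists. These include alveolar type 2 genes, with a median of 0.46 and members in both directions, from Sftpc, 151-fold higher (145 to 158), to Cxcl15, 2.57-fold lower. Alveolar capillary genes had a median of -0.69, with 5 genes over 2-fold higher and 7 lower, among them Calcrl, 5.33-fold lower (5.24 to 5.43). Alveolar macrophage genes had a median of -0.16. Immediate early genes, which respond to stimulation and handling, had a median of 0.54, with 6 of 15 genes over 2-fold higher and 0 lower. Dusp1, at 198 and 180 TPM, and Klf2, at 168 and 195 TPM, had the highest means of the list and differed little. The next by mean TPM differed more and in opposite directions, with Klf4 at 150 and 74.6 TPM and Btg2 at 66.3 and 102.7 TPM. No tested erythroid or cardiac gene was at 0 in either library, so setting genes at 0 to 3 counts tests nothing for these lists. Matching random lists on gene length too placed the erythroid list at percentile 96.1, inside the range. It placed 4 further lists above the range, those of alveolar type 1 cells (99.9), fibroblasts and matrix (99.1), alveolar type 2 cells (98.8) and B and plasma cells (97.7).

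**Figure D2:**
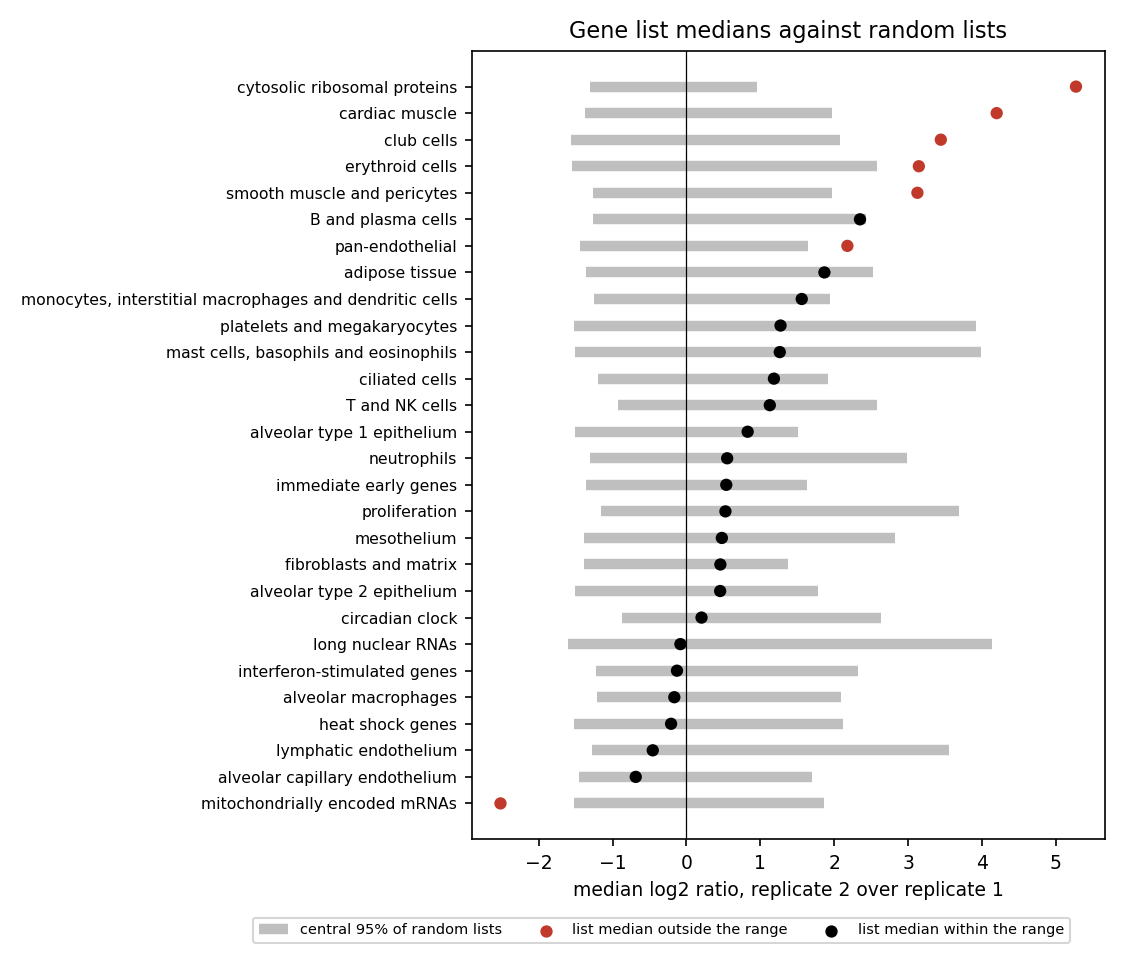
Median log2 ratio of replicate 2 over replicate 1 for 28 gene lists (points) against the central 95% of medians of 10000 random lists matched on size and expression (grey bars), with red points outside the range. Ribosomal protein genes are highest at 5.27 and mitochondrially encoded mRNAs lowest at -2.52.

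The ratio between the libraries followed the GC content of the transcripts. Protein-coding genes of the lowest GC decile, 18.1% to 41.3% GC, were detected slightly more often in replicate 1, at 37.9% of 2145 genes (exact 95% interval 35.8 to 40.0), than in replicate 2, at 33.1% (31.1 to 35.1). In the highest decile, 58.0% to 76.5% GC, 22.5% of genes (20.7 to 24.3) were detected in replicate 1 and 66.6% (64.5 to 68.6) in replicate 2. The median log2 ratio was -2.05 in the lowest decile, where 763 of 778 genes tested were over 2-fold lower in replicate 2, and 5.15 in the highest, where 1220 of 1314 genes were over 2-fold higher, or 4.86 with genes at 0 set to 3 counts. Genes of the mitochondrial list had a GC content of 31.9% to 41.1%. Igfbp6, Eln, Rps15, Cldn5, Ager and Cbr2 had 60.7%, 58.8%, 60.1%, 60.4%, 59.3% and 57.5%, and Calcrl and Cxcl15 had 38.7% and 41.5%. Across 14107 genes the log2 ratio and the GC content had Pearson's r = 0.778 and Spearman's rho = 0.834. The TPM itself was lower at higher GC content across genes in replicate 1 (r = -0.54) and varied little with it in replicate 2 (r = 0.16), and the relation of the log2 ratio to transcript length was weaker, with rho = -0.27. With the GC trend subtracted, an alternative chosen after seeing the data, the median of pan-endothelial genes went from 2.18 (bootstrap interval -0.44 to 4.32) to 0.02 (-0.70 to 0.82) and that of mitochondrially encoded mRNAs from -2.52 (-3.04 to -2.37) to -0.25 (-0.48 to -0.17), both inside the range of random lists. Immediate early genes, at -1.72, and clock genes, at -0.95, then lay below it. The window measure of GC content gave other calls, with mitochondrially encoded mRNAs still below the range at -1.23 (-1.47 to -0.82) and immediate early and clock genes inside it at 0.19 and 0.09. With it cardiac muscle genes, at 0.57 (-0.15 to 1.57), club cell genes, at 0.64 (-0.38 to 2.31), smooth muscle and pericyte genes, at 0.08 (-0.47 to 2.73), and pan-endothelial genes, at -0.41 (-1.29 to 0.59), came inside the range.

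**Figure D3:**
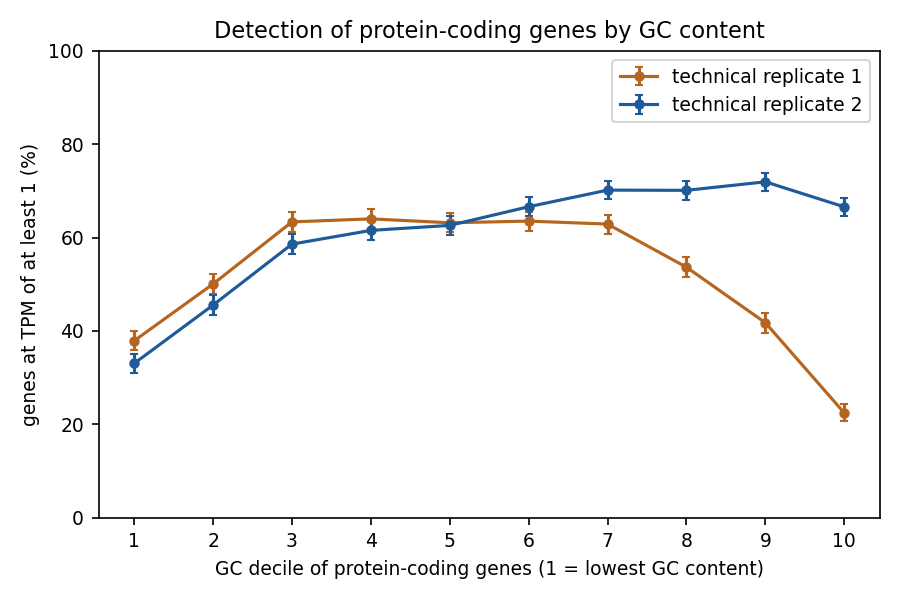
Percentage of protein-coding genes at a TPM of at least 1 (y axis) in 10 classes of rising GC content (x axis) for technical replicate 1 (brown) and technical replicate 2 (blue), with exact 95% intervals. Detection is slightly higher in replicate 1 in the lowest class, at 37.9% against 33.1%, and nearly equal in class 5, at 63.2% and 62.6%. From class 7 up, where it is 62.9% and 70.2%, detection is higher in replicate 2 with intervals that do not overlap. The gap is widest in the highest class, where 22.5% and 66.6% of genes were detected.

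**Figure D4:**
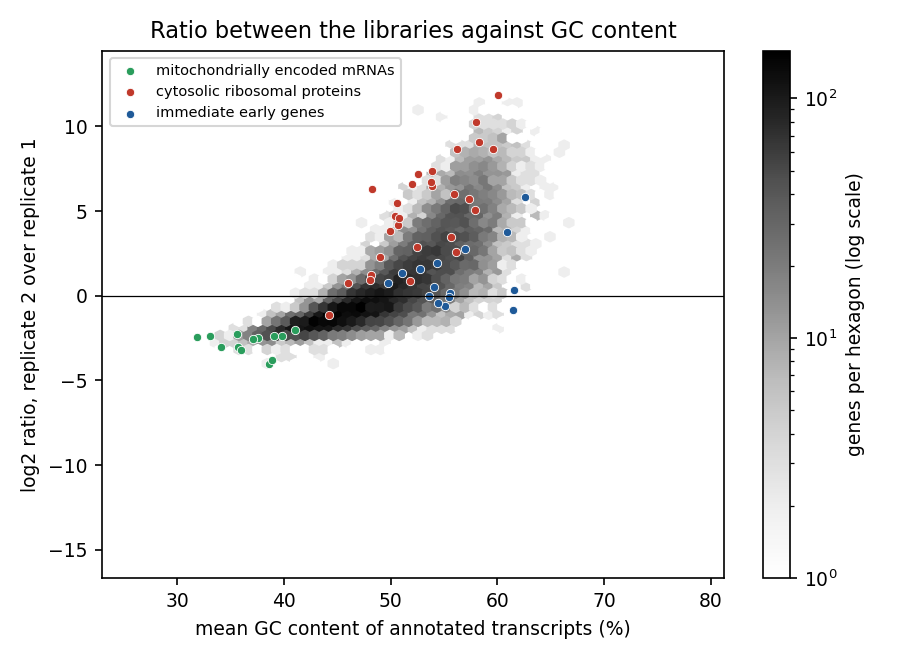
Log2 ratio of replicate 2 over replicate 1 (y axis) against the mean GC content of a gene's annotated transcripts (x axis, percent) for 14107 genes, shaded by the number of genes per hexagon on a log scale, with members of 3 gene lists as coloured points. The ratio rises with GC content, and the mitochondrially encoded mRNAs lie at the low end of both axes.

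The libraries also gave different main transcripts for many genes. In 3706 of 5692 genes with a mean TPM of at least 10 and more than 1 annotated transcript, the transcript of highest TPM was the same in both libraries, or 65.1% (exact 95% interval 63.9 to 66.3). Among 66 of the named genes it differed in 28. For Sftpa1, the 2854-base transcript Sftpa1-202, with 44.0% GC, held 100% of the gene's TPM in replicate 1 and 22.7% in replicate 2, where the 851-base Sftpa1-201, with 52.9% GC, held 77.3%. Hbb-bs, Cbr2, Rps15, Rps14 and Sftpb were the other examples of highest expression. For Hbb-bs, the transcript Hbb-bs-202 held 98.7% in replicate 1 and 2.40% in replicate 2, and Hbb-bs-201 held 1.35% and 97.6%. In Rps15 the estimate for replicate 1 rests on 3 counts.

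Genes of the sex chromosomes matched the label female in both libraries. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), was at 231 TPM in replicate 1 and 65.0 TPM in replicate 2, from 10012 and 3449 counts, and has 41.8% GC. Of the Y-linked genes, Kdm5d and Uty had 0 counts in both libraries, and Ddx3y and Eif2s3y had 1 count each in replicate 1 and 0 in replicate 2. The antisense gene Tsix had 2 and 9 counts, and its reads cannot be told from those of Xist where counting did not use strand.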

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

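Alternatives that subtract a trend on GC content or keep the middle GC decile were chosen after seeing the data; the others were fixed beforehand. With the GC trend subtracted the medians of immediate early and clock genes turned from 0.54 and 0.20, inside the random range, to -1.72 and -0.95, below it, and with the window trend that of pan-endothelial genes turned from 2.18, above it, to -0.41, inside it. Other medians that stayed inside the range also changed sign under some settings. Genes detected in both libraries numbered 7039 at a TPM of at least 5 and stayed within 1.5 times of the main count under the others. The share of genes over 2-fold apart was 64.8% by total counts, 69.1% by TPM ratio, 65.8% with a prior of 5 counts and 70.0% without the filter, and the share beyond counting noise was 89.1% by total counts, 68.0% without the filter and 94.9% at a TPM of at least 10, where other genes are tested. Pearson's r was 0.716 and 0.710 with pseudocounts of 0.01 and 10, 0.840 over all genes, since genes at 0 in both enter, 0.563 at a mean TPM of at least 1 and 0.602 over transcripts. Dominant transcripts were the same in 70.1% of genes with a margin of 10 points. After the GC trend was subtracted, the share over 2-fold apart was 40.8%, or 34.6% with the window measure, r at a mean TPM of at least 1 was 0.791, and 11 lists lay outside the random range, 5 of them with the same call as before; the calls of pan-endothelial genes and mitochondrially encoded mRNAs ended, and ciliated, monocyte and dendritic, B and plasma cell and adipose lists came to lie above it. In the middle GC decile 44.6% of genes were over 2-fold apart, 82.5% differed beyond counting noise and the coefficient of variation was 0.621. Scaling, prior and filter left all 7 list calls in place, and at a mean TPM of at least 5 the monocyte and dendritic and the adipose lists were also above the range. Matching on length kept 6 calls, without the erythroid list, and added 4 above. The window measure kept 3 calls, since club cell (0.64), cardiac (0.57), smooth muscle (0.08) and pan-endothelial medians came inside, and added alveolar type 2 genes above and long nuclear RNAs below. With 1 library left out, genes detected ranged from 12131 to 14096, the share of TPM of the cell type lists from 5.17% to 27.1% and Xist from 65.0 to 231 TPM. The coefficient of variation was 1.00 to 1.03 under other scaling and filters. The cause of these changes was not tested except where stated. No paired analysis was possible because the design has 1 group. Depth limits genes near 3 counts.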

Other observations

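Tests chosen only after the result was seen were those of sequencing depth, of cell mix as the whole of the difference, and both tests of the mitochondrial mRNAs; subtracting a GC or window trend was also chosen after seeing the data.

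Genes of cell state were expressed at moderate levels and followed no single direction between the libraries. The heat shock genes, 10 of 10 detected in both libraries, summed to 2927 TPM in replicate 1 and 1825 TPM in replicate 2, led by Hspa8 at 842 and 940 TPM and Hsp90aa1 at 959 and 228 TPM. Proliferation genes were low, at 14.6 and 15.6 TPM in sum over 12 genes, with Top2a at 2.80 and 2.10 TPM and Birc5 at 2.69 and 2.59 TPM. Interferon-stimulated genes summed to 243 and 462 TPM, with Bst2 at 5.35 and 260 TPM. Clock genes summed to 167 and 145 TPM, with Nr1d2 at 54.0 and 9.72 TPM, Arntl at 24.6 and 14.9 TPM and Tef at 14.97 and 32.6 TPM. Their list medians, -0.21 for heat shock, 0.53 for proliferation, -0.13 for interferon-stimulated and 0.20 for clock genes, all lay within the central 95% of random lists. With the GC trend subtracted clock genes were at -0.95 (-1.25 to -0.14), below that range at percentile 0.6, and with the window trend at 0.09, inside it.

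Small structured RNAs, histones and long nuclear RNAs were present at varied levels. The small structured RNAs summed to 1.74 TPM in replicate 1 and 217 TPM in replicate 2, mostly Rn7sk, with 3 and 431 counts, a ratio of 113 (38.3 to 549). Replication-dependent histones summed to 366 and 284 TPM, mainly Hist1h2bc at 342 and 198 TPM, and 8 of the 12 were below a TPM of 1 in both libraries. Of the long nuclear RNAs, Malat1 was at 939 and 98.2 TPM, Neat1 at 367 and 303 TPM, and Gm26917, with 70.7% GC, had 0 and 446 counts, at least 117-fold higher in replicate 2. The median of the long nuclear RNAs, -0.08, lay within the random range, and with the window trend subtracted it was -1.44, below that range.

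The ratio between the libraries rises with GC content. A difference in depth is argued against, since totals were close and 240 genes with at least 100 counts in replicate 2 were at 0 in replicate 1, and so is cell mix as the whole of the difference, since list membership alone had an adjusted R2 of 0.00696 (0.00293 to 0.189) for 199 cell type genes, against 0.646 for the GC trend. A candidate explanation is loss of GC-rich fragments in making or sequencing replicate 1, which predicts the same trend within genes. Across 5163 pairs of isoforms of 1 gene, the difference in log2 ratio rose with the difference in GC content (rho = 0.350, 0.327 to 0.372), and 605 of 732 pairs at least 5 GC points apart, 82.7%, moved with GC. A different cell mix beside the trend stays open, since list membership added 0.0314 to the adjusted R2 with an interval of 0.0196 to 0.114 that passes the bound of 0.1 set for it.

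Mitochondrially encoded mRNAs take a larger share of replicate 1. The GC trend of the nuclear genes may account for this, since the 13 mRNAs lay a median of -0.25 (-0.48 to -0.17) from it on the log2 scale and 813 nuclear genes of the same GC range had a median ratio of -2.07 against their -2.52. The measure of GC matters, however, because from the window trend they lay at -1.23 (-1.47 to -0.83), so whether GC content is the whole cause cannot be told apart from a larger mitochondrial RNA content of the material in replicate 1. Reads shared with the pseudogene copies on chromosome 1 keep the level of each mRNA uncertain. The copies were lower in replicate 2 too, Gm28661 by 4.37-fold, Gm10925 by 6.91-fold, Gm28437 by 3.82-fold and Gm28438 by 6.65-fold. Gm28439, annotated as a pseudogene beside them, had 15239 counts in replicate 1 and 0 in replicate 2. Its difference can depend on how reads were divided in each library. A move of reads from these copies to the 13 mRNAs in replicate 1 is therefore argued against as the source of the larger share. No biological explanation was tested, since the design has 1 group.

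The listed ribosomal protein mRNAs lie above and immediate early mRNAs below the GC trend. Their medians were 3.71 (1.84 to 4.74) and -1.72 (-2.94 to -0.35) after it was subtracted. Rps24, a ribosomal protein gene outside the list, was then at -0.46. Reads given to processed pseudogenes in replicate 1 are argued against for the ribosomal proteins, since 5349 such pseudogenes held 17218 counts in replicate 1 and 26225 in replicate 2, a scaled surplus of -0.013 of the reads lacking. Loss set by the most AT-rich stretches of a transcript, not by its mean, could apply, since the window measure removed 72.5% of the variance of the ratios against 63.3% for the mean. With it the median of immediate early mRNAs became 0.19 (-0.58 to 0.73), 0.108 of its former distance (0.0176 to 1.29), and that of ribosomal protein mRNAs 2.91 (1.82 to 3.82), 0.783 of it (0.549 to 1.14). Both intervals pass 1, so these tests decide neither part, and the ribosomal protein mRNAs stayed above the random range under each measure.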
